A study of Mus musculus with 59 samples.

How the data were processed

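The data are RNA sequencing of total RNA from the ventral tegmental area of male mice, 59 libraries in 8 groups: cocaine and saline in each of 4 paradigms. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were made with a TruSeq RNA kit. Whether that kit kept strand is not stated in the labels. The authors deposited one table of FPKM, by gene symbol and library. Per the submitters' processing notes the tools named are Bowtie and Cuffnorm and the genome build is mm10. Versions, the gene annotation, filters and the scaling used by Cuffnorm are not given in the sources used here. All 59 columns of the table were used. Each column was mapped to its group by its name. The columns carry numbers counted from 0 that could not be tied to the replicate numbers in the labels, so columns are replicates of a group without pairing, and libraries are named by their group and column number.

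FPKM divides fragments by transcript length and library total, so a few abundant transcripts, a shift in fragment length or a GC bias can move the values of many genes. Sums of FPKM per library ran from 398577 to 457508, so totals are similar but not fixed. The read depth is unknown. Low values were searched for steps that whole reads would leave: the most frequent step held between 3.41% and 14.9% of the low genes of a library. In 26 libraries it held at least 5 times as many genes as the median position. None of these was of self-administration, where the highest ratio was 4.55. Reads were judged not recoverable from this, which was not tested, so no count test was run and no counting interval is given. No gene at 0 was treated as absent, only as listed at 0. The self-administration libraries stood apart from all others along the first principal component, and the labels give no batch.

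Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 also names, matched by symbol. Of 24346 symbols, 23970 (98.5%) matched. The annotation the authors used may draw gene limits elsewhere. Reads of overlapping genes, opposite-strand partners, pseudogenes and near-identical copies could have been split between them, a limit that also holds for genes beside which it is not repeated, such as ribosomal protein genes.

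Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the libraries of a comparison were tested. Cocaine and saline were compared within each paradigm by limma 3.58.1 in R 4.3.3 (linear fit and empirical Bayes with trend and robust options, two-sided), and p-values were adjusted by Benjamini and Hochberg over the genes of the comparison, with 0.05 as the threshold. A second, descriptive limit was an unadjusted p under 0.05 together with at least 1.3-fold. The average effect of cocaine was fitted over all 8 groups with the paradigm as an additive term. The 6 differences between cocaine effects came from one fit of all 8 group means, and the saline groups were compared by a moderated F test. Correlations and overlaps between paradigms were set against 100 relabellings of cocaine and saline within paradigms. These comparisons, the lists and the rule for named genes were fixed before the data were examined.

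Gene lists, 30 in number, were fixed for dopamine neurons, dopamine receptors and turnover, immediate early genes, glucocorticoid response, circadian clock, GABA and glutamate transmission, neuropeptides and opioid system, neurotrophic signalling, nicotinic receptors, excitability channels, chromatin regulators, oligodendrocytes and myelin, astrocytes, microglia, endothelium and pericytes, red blood cells, choroid plexus and ependyma, serotonin neurons, hypothalamus and mammillary body, forebrain, pituitary, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosomal proteins, ER chaperones, heat shock, interferon and inflammation, extracellular matrix and sterol synthesis. The pituitary and mitochondrially encoded lists had too few tested members and were not tested, which left 112 tests of 28 lists in 4 paradigms. Each was tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, each adjusted over the 112 tests. Counts of members are given adjusted over the list alone and over all genes tested. A list's level is the mean of log2(FPKM + 1) over its tested members in a library. Lists can share genes: Per1 is in both the glucocorticoid and the clock list, and Drd2 in both dopamine lists.

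Named genes were up to 10 per direction with the largest change among those past the threshold, filled up to 10 by the smallest unadjusted p among genes with at least 1.3-fold. To these were added 2 to 4 members with the smallest p of each list described, Th, Slc6a3, Slc18a2 and Drd2 in every paradigm, up to 10 genes of the average effect, up to 3 per difference between paradigms, up to 10 genes past unadjusted p under 0.05 in the same direction in at least 3 paradigms, and up to 6 between saline groups. Predicted genes with only a Gm, Rik or locus name were counted but not named unless nothing else filled the place. Some genes that the rule names are not reported here. Further members of the glucocorticoid and clock lists are named to give all those that passed or did not, and were chosen after their values were seen, as were genes called under single alternatives. Th, Slc6a3, Slc18a2 and Drd2, and Fgf20 once its result was seen, were also tested by exact two-sided permutation within each paradigm.

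The limma steps were tested on simulated data in 20 draws per paradigm: real gene means plus the libraries' own residuals in shuffled order. In each draw 200 genes were changed at once, by 1.3-, 1.5-, 2- or 3-fold on the log2(FPKM + 1) scale. Recovered were 70.9% of genes changed by 1.3-fold and 90.9% by 1.5-fold over the 13164 genes of acute, 76.3% and 92.7% over 13190 of chronic, 71.6% and 90.6% over 13135 of conditioning, and 74.0% and 92.7% over 13130 of self-administration. Between 2.11% and 5.32% of calls were false. The stronger changes loosen the adjusted threshold for the weaker ones, unlike the real comparisons within paradigms, where no gene passed. These rates are therefore not the power for a few small changes, and the lack of calls does not show that such changes are absent. In draws without any effect, preset-correlation camera called on average 7.45, 7.65, 6.25 and 8.1 of 28 lists (adjusted within the paradigm), while fry called 0.05, 0, 0.05 and 0. So a call by preset-correlation camera alone is weak evidence. The glucocorticoid list shifted by 0.3 was found by preset-correlation camera in 100% of draws, by fry in 45%, 95%, 60% and 15%, and by camera with an estimated correlation in 35%, 65%, 55% and 45%.

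Alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, upper-quartile scaling, plain empirical Bayes, library weights (arrayWeights), all groups in one fit, the myelin list as covariate, and leaving out each library or paradigm. The replicate block was planned and not run. Further ones were added after the data were seen: setting aside the 6 libraries least correlated with any other, the dopamine neuron list as covariate, Fgf20 without each library in turn, exact permutation of list levels, the called lists without each library of their paradigm in turn, genes matched on length and GC content, and a correction for GC content and transcript length within each library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.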

Results

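Ribonucleic acid was sequenced from the ventral tegmental area (VTA), the midbrain region that holds the dopamine neurons projecting to the striatum and cortex, of male mice that had received cocaine or saline. Cocaine blocks the dopamine transporter, and it was given in 4 ways: acutely by injection in the home cage, chronically by injection in the home cage, in a conditioning procedure, and by intravenous self-administration. Each paradigm had its own saline group. The 59 libraries fell into 8 groups: 5 cocaine and 6 saline libraries for acute, 6 and 6 for chronic, 6 and 6 for conditioning, and 15 and 9 for self-administration. The labels do not say that the samples were separate animals, so p-values measure only the spread between these samples, which may be technical. The dose, the number of doses, the kind of conditioning and the time between the last dose and tissue collection were not in the labels. The deposited values are FPKM (fragment counts scaled to transcript length and library size) for 24346 gene symbols. The read depth behind each library is unknown, and no counting interval was computed. Each library listed between 5689 and 7925 symbols at 0, and no pair of libraries held identical values. Differences are cocaine minus saline on the log2(FPKM + 1) scale with their standard error (SE), which understates the change of genes with low values. FPKM values are given as mean ± SD.

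The first principal component held 37.9% of the variance of log2(FPKM + 1) and parted every self-administration library from every library of the other 3 paradigms. Its scores ran from -34.6 to -12.6 in self-administration and from 6.93 to 21.4 elsewhere. Cocaine and saline libraries were intermixed within each paradigm. The second component held 7.48%.

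**Figure D1:**
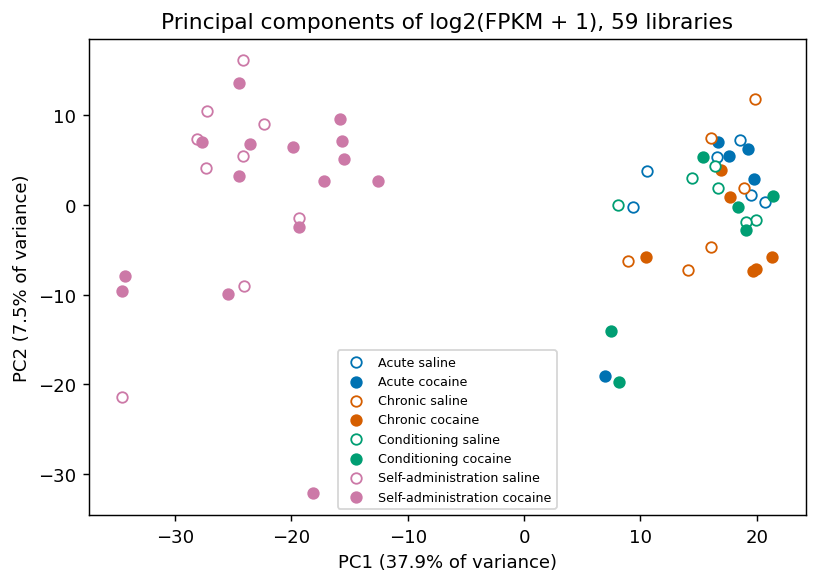
Scores of the 59 libraries on the first (x axis, PC1) and second (y axis, PC2) principal components of log2(FPKM + 1), with the percent of variance on each axis. Colours mark the paradigm, filled points cocaine and open points saline. All self-administration libraries lie at negative PC1 scores and all others at positive ones.

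The first comparison asked what cocaine did on average across the 4 paradigms. Fgf20, a fibroblast growth factor known to support dopamine neurons, fell by 0.68 ± 0.11 (SE) on the log2 scale (limma adjusted p = 0.00104 over 13186 genes). Its FPKM after cocaine and saline was 0.919 ± 0.615 (n = 5) and 2.35 ± 0.696 (n = 6) in the acute paradigm, and 0.955 ± 0.331 (n = 6) and 2.29 ± 1.37 (n = 6) in the chronic one. In conditioning it was 0.832 ± 0.526 (n = 6) and 2.52 ± 1.55 (n = 6), and in self-administration 0.945 ± 0.401 (n = 15) and 1.88 ± 1.16 (n = 9). Cocaine libraries lay below their saline median in 5 of 5, 6 of 6, 6 of 6 and 13 of 15 cases, and no library listed Fgf20 at 0. Exact two-sided permutation tests per paradigm gave p = 0.00216, 0.0433, 0.0130 and 0.0054 in that order, or 0.00866, 0.0433, 0.0173 and 0.0108 after Benjamini-Hochberg adjustment over the 4. These 4 tests were run on a gene picked from the same libraries. In GRCm38 coordinates Fgf20 spans 40279166 to 40308331 on the minus strand of chromosome 8 and is annotated as protein coding.

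No other gene passed in this fit. At unadjusted p under 0.05 there were 1689 genes (853 higher, 836 lower) where 659 would be there by chance if genes were independent. Next in order came Trib2, a pseudokinase (-0.13 ± 0.03, adjusted p = 0.185), Timm10, an import chaperone of mitochondria (0.15 ± 0.03, adjusted p = 0.198), Jarid2, a subunit of a chromatin-silencing complex (-0.11 ± 0.03), and Ccdc50 (-0.11 ± 0.03). After them came Fam117b (-0.13 ± 0.03), the microglial purine receptor P2ry13 (-0.20 ± 0.05), Maneal (0.10 ± 0.03), the methyltransferase Smyd3 (-0.14 ± 0.03) and the GABA-A receptor subunit Gabrg1 (-0.17 ± 0.04), the last at adjusted p = 0.216. Without the acute libraries, Fgf20 lay at -0.64 with adjusted p = 0.0646, so the call then ended. Weighting libraries by their quality called 41 genes, Fgf20 and Trib2 first.

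**Figure D2:**
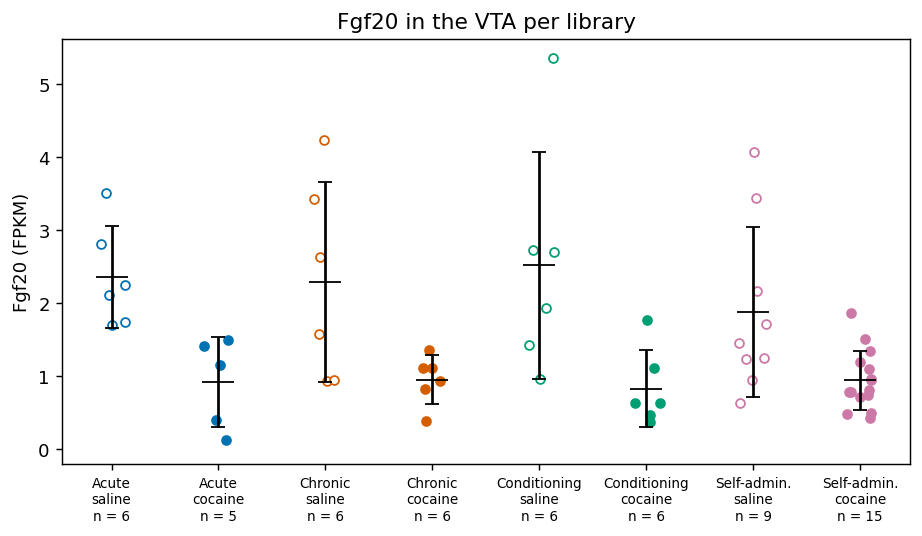
Fgf20 in FPKM (y axis) in each library of the 8 groups (x axis), with saline as open and cocaine as filled points. Horizontal bars give the group mean and whiskers the SD; the cocaine means lie between 0.832 and 0.955 and the saline means between 1.88 and 2.52.

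In the lists of genes fixed before the data were examined, the average effect was a mean of -0.066 for the circadian clock list (16 of 17 members negative), 0.078 for the nuclear genes of oxidative phosphorylation (52 of 53 positive) and -0.36 for markers of hypothalamus and mammillary body (8 of 8 negative). The camera test with a preset correlation gave adjusted p = 6.12e-05, 1.40e-14 and 0.00307 over 28 lists. These became adjusted p = 0.353, 0.444 and 0.444 with an estimated correlation, and fry, which asks whether a list moves one way, gave adjusted p = 0.0452, 0.129 and 0.144. The GABA transmission list had a mean of -0.056 with 15 of 21 members negative. Its adjusted p was 0.00310 with the preset correlation, adjusted p = 0.366 with an estimated correlation, and 0.0639 with fry. The preset correlation also called myelin genes (mean 0.070, 15 of 18 positive), microglia (-0.059, 14 of 17 negative), immediate early genes (0.071, 14 of 22 positive), chromatin regulators (-0.023, 23 of 31 negative) and ribosomal proteins (0.0085, 45 of 57 positive). Their adjusted p of 0.00307, 0.0213, 0.0397, 0.0397 and 0.0397 became adjusted p = 0.765, 0.835, 0.786, 0.580 and 0.835 with an estimated correlation, and fry called none of these 5 (lowest adjusted p = 0.221).

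After acute injection in the home cage, markers of dopamine neurons lay lower and immediate early genes higher than in saline, with no single gene past the threshold. The dopamine neuron list had a mean difference of -0.34, with 19 of 20 members negative, its level being 5.07 ± 0.62 (SD, n = 5) after cocaine and 5.40 ± 0.25 (n = 6) after saline. Its members include the dopamine transporter Slc6a3 (261 ± 165 against 342 ± 80.9 FPKM), the nicotinic receptor subunits Chrna6 (-0.55 ± 0.37) and Chrnb3 (-0.42 ± 0.29), and the vesicular monoamine transporter Slc18a2 (109 ± 58.3 against 140 ± 35.0 FPKM). The immediate early list, genes transcribed quickly in active neurons, had a mean of 0.15 with 17 of 21 members positive: Fos was 17.0 ± 3.54 after cocaine and 11.0 ± 4.26 FPKM after saline, Nr4a1 6.76 ± 1.61 and 5.05 ± 0.990, Nr4a3 2.09 ± 0.277 and 1.505 ± 0.431, and Ier2 5.28 ± 0.495 and 4.09 ± 0.763. Myelin and oligodendrocyte markers were positive in 18 of 18 (mean 0.11), among them Trf (0.21 ± 0.10) and Cnp (0.16 ± 0.08).

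The interferon list had a mean of 0.083, and 3 of its 15 members rose when p-values were adjusted over the list alone and 0 over all genes tested: Bst2, an antiviral membrane protein (0.24 ± 0.06), and the class I histocompatibility genes H2-D1 (0.16 ± 0.05) and H2-K1 (0.17 ± 0.06), relatives that can share reads with each other. Ribosomal protein genes were positive in 50 of 57 (mean 0.059, with Rpl41 at 0.16 ± 0.04 and Rpl37 at 0.14 ± 0.04) and oxidative phosphorylation genes in 49 of 53 (mean 0.062, with Ndufb10 at 0.17 ± 0.07 and Cox4i1 at 0.12 ± 0.05). No member of the dopamine neuron, immediate early, oligodendrocyte, ribosomal or oxidative phosphorylation lists passed, either adjusted over the list alone or over all genes tested. Preset-correlation camera called these 6 lists, with adjusted p from 2.97e-08 to 7.58e-04 over the 112 tests of 28 lists in 4 paradigms. All were lost: the ribosomal and interferon lists had adjusted p = 0.659 with an estimated correlation, the dopamine neuron list adjusted p = 0.666, and the other 3 adjusted p = 0.664. Fry called 0 lists in this paradigm. Much of this rested on the least correlated acute library, number 4 of the cocaine group. Without it, a setting added after the data were seen, the means were -0.15 for the dopamine neuron list (adjusted p = 0.128 with the preset correlation) and 0.0028 for oxidative phosphorylation (adjusted p = 0.373), so both calls ended. The ribosomal mean was then 0.031 and the interferon mean 0.046, with the calls kept, and the myelin mean ran from 0.069 without cocaine library 0 to 0.17 without cocaine library 1. Library weights gave the dopamine neuron list a mean of -0.087 (adjusted p = 0.349). Short transcripts were higher across the transcriptome here (median 0.036 in the tenth of genes with the shortest and -0.048 in that with the longest), and above genes matched on length and GC content the ribosomal mean was 0.034 ± 0.0084 and the oxidative phosphorylation mean 0.036 ± 0.01 (SE over members).

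Over 13164 genes, limma called 0 in the acute paradigm (smallest adjusted p = 0.9846). At unadjusted p under 0.05 there were 515 genes, 286 higher and 229 lower, where 658 would be there by chance, and 16 of them also differed by at least 1.3-fold. Such chance counts, here and in the other paradigms, are those for independent genes. Random splits of the libraries, given further below, varied widely, with up to 144 genes past both limits in acute. Those filling the places of the naming rule all had adjusted p = 0.9846. On the lower side were Fgf20 (-0.85 ± 0.21), Grin2b, a subunit of the NMDA glutamate receptor (-0.38 ± 0.15), the zinc finger factor Rreb1 (-0.51 ± 0.22), the brain collagen Col25a1 (-0.44 ± 0.22), Dlk1, a Notch-related membrane protein (-0.40 ± 0.22), Pet117 (-1.03 ± 0.51), Mrln (-0.58 ± 0.26), the small nucleolar RNA Snord15b (-1.83 ± 0.77) and Mir686 (-3.68 ± 1.69). On the higher side were Fos, the heat shock protein Hspa1a (0.75 ± 0.33), whose reads can be shared with its near-identical copy Hspa1b (0.71 ± 0.45), Cd74, the invariant chain of class II histocompatibility (0.49 ± 0.19), Cpne9 (0.40 ± 0.19), Mir8094 (2.16 ± 0.99) and Toporsos (0.63 ± 0.19), which is named as the opposite-strand partner of Topors and cannot be told from it without strand. Single libraries carried part of several differences. Without cocaine library 4 they were -0.28 for Col25a1, -0.24 for Dlk1, -0.61 for Pet117, -0.37 for Mrln, -0.32 for Chrna6 and -0.23 for Chrnb3, and without cocaine library 1 they were 0.29 for Cd74 and 0.24 for Cpne9. Mir6990, Mir1946a, Mir374b and Mir7-1 were listed at 0 in every saline library and Mir8103 in every cocaine library.

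Chronic injection in the home cage was accompanied by higher levels of glucocorticoid-responsive genes, which the glucocorticoid receptor induces when stress hormone binds it. All 18 members of that list were positive (mean 0.34, level 4.06 ± 0.12 after cocaine and 3.72 ± 0.076 after saline, SD, n = 6 and 6). Adjusted over the list alone 15 of the 18 rose, and 0 did adjusted over all genes tested. Sgk1, a kinase induced by glucocorticoids, was 134 ± 17.5 FPKM after cocaine and 83.7 ± 15.1 after saline (0.68 ± 0.12). Arrdc2, of the arrestin-domain family, was 16.4 ± 1.44 and 11.3 ± 1.32 (0.50 ± 0.07), Ddit4, an inhibitor of mTOR signalling, 50.2 ± 5.37 and 38.6 ± 2.31 (0.37 ± 0.07), and Plin4, a lipid droplet protein, 2.35 ± 0.642 and 1.14 ± 0.338 (0.64 ± 0.13). Also among the 15 were the cell cycle inhibitor Cdkn1a (0.57 ± 0.13), the sulfotransferase Sult1a1 (0.50 ± 0.12), the metallothioneins Mt2 (0.41 ± 0.08) and Mt1 (0.33 ± 0.08), Tsc22d3 (0.27 ± 0.07), Nfkbia (0.35 ± 0.09) and Fkbp5 (0.18 ± 0.07). The 3 that did not pass were Zbtb16 (0.10 ± 0.19), Map3k6 (0.15 ± 0.10) and Sgk3 (0.08 ± 0.06).

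Preset-correlation camera gave adjusted p = 9.80e-22 for this list, fry adjusted p = 0.0150, and camera adjusted p = 0.0612 with an estimated correlation. An exact permutation of the list's level between the 12 chronic libraries, a test added after the data were seen, gave p = 0.00216, or 0.176 after adjustment over the 112 tests. Every cocaine level (lowest 3.91) lay above every saline level (highest 3.84), so this p was the smallest that the test can give. Adjustment over 112 tests could be passed only if several lists reached so small a p. Sgk1 spans 21882184 to 21999903 on the plus strand of chromosome 10, and Arrdc2 70835129 to 70839720 on the minus strand of chromosome 8 (GRCm38).

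**Figure D3:**
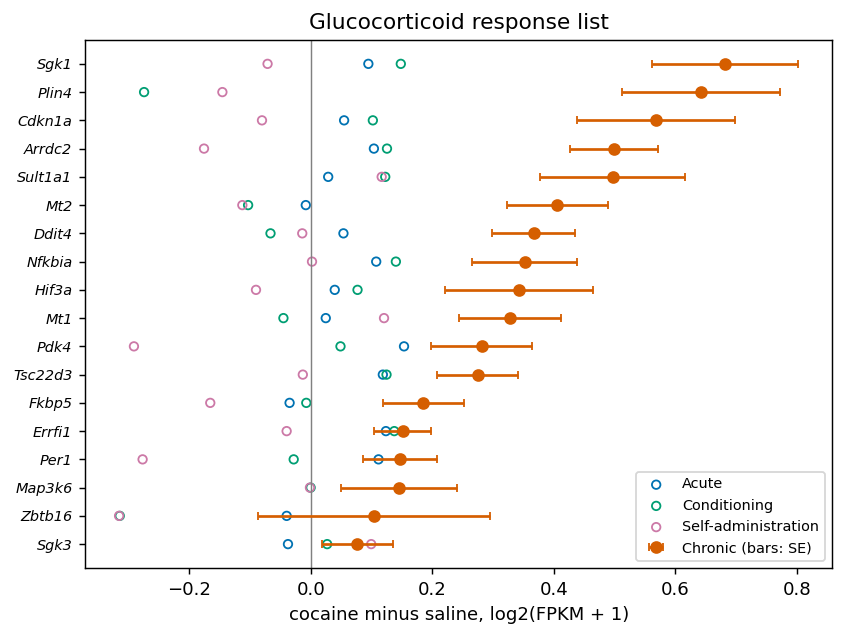
Difference between cocaine and saline on the log2(FPKM + 1) scale (x axis) for the 18 genes of the glucocorticoid response list (y axis). Filled points with SE bars are the chronic paradigm, open points the other 3 paradigms; all 18 chronic points lie above 0, from 0.08 for Sgk3 to 0.68 for Sgk1.

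Other lists also differed in the chronic paradigm. Oxidative phosphorylation genes were positive in 53 of 53 (mean 0.15), 11 of them rising when adjusted over the list alone and 0 over all genes tested: Cox7b, a subunit of cytochrome c oxidase, was 200 ± 14.9 FPKM after cocaine and 162 ± 11.4 after saline, Atp5j2, of ATP synthase, 443 ± 16.7 and 382 ± 22.5, and Ndufa7, of complex I, 158 ± 5.07 and 136 ± 6.35. Ribosomal protein genes were positive in 56 of 57 (mean 0.091, 4 rising adjusted over the list alone and 0 over all genes tested), with Rpl41 at 0.21 ± 0.05 and Rpl37 at 0.23 ± 0.06. Markers of endothelium and pericytes were negative in 13 of 16 (mean -0.13). Of these, 2 fell adjusted over the list alone and 0 over all genes tested: the tight junction protein Cldn5 (22.3 ± 1.51 against 28.5 ± 4.52 FPKM) and the angiopoietin receptor Tek (3.53 ± 0.340 against 4.15 ± 0.251). Immediate early genes had a mean of 0.17 with 15 of 21 positive and 0 past either adjustment, including Fos (16.9 ± 3.07 against 10.7 ± 5.16 FPKM), Nr4a1 (0.51 ± 0.15) and the phosphatase Dusp1 (0.25 ± 0.07). Preset-correlation camera called all 4, with adjusted p = 2.39e-23, 9.33e-15, 1.31e-05 and 0.00492. None held, with adjusted p = 0.618, 0.659, 0.664 and 0.666 with an estimated correlation. The immediate early call also ended without cocaine library 2 (mean 0.13) or saline library 3 (0.12) or 4 (0.11). Short transcripts were higher across the whole transcriptome in this comparison too: the median difference was 0.068 in the tenth of genes with the shortest transcripts and -0.041 in that with the longest. Above genes matched on length and GC content the oxidative phosphorylation mean was 0.11 ± 0.0097 and the ribosomal mean 0.046 ± 0.015 (SE over members). Quantile normalization brought the oxidative phosphorylation mean to 0.078.

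Over 13190 genes limma called 0 in the chronic paradigm, with the smallest adjusted p at 0.106 for Arrdc2. At unadjusted p under 0.05 there were 974 genes (548 higher, 426 lower, 660 by chance), of which 32 differed by at least 1.3-fold. Beside the glucocorticoid-responsive genes, the higher side held Arl4d (0.47 ± 0.13), Smim3 (0.48 ± 0.11) and neuropeptide B, Npb (0.39 ± 0.12). The lower side held Fabp7, a fatty acid carrier of astrocytes (36.5 ± 5.42 against 52.2 ± 9.93 FPKM), the cystine transporter Slc7a11 (-0.43 ± 0.14), the glutamine transporter Slc38a5 (-0.46 ± 0.12), the interferon-induced Gbp4 (-0.41 ± 0.11), the membrane protease Mmp14 (-0.40 ± 0.12), Igsf1 (-0.51 ± 0.16), Foxb1, a factor of the mammillary body (-0.46 ± 0.15), the nuclear RNA Neat1 (-0.39 ± 0.13), Snora70 (-2.09 ± 0.68) and the pseudogene Pisd-ps1 (-0.41 ± 0.09), whose reads can be shared with Pisd. Their adjusted p ranged from 0.411 to 0.578. Without chronic cocaine library 0, limma called Ddit4 (adjusted p = 0.0174), and without chronic saline library 0 Arrdc2 (adjusted p = 0.0368).

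In the conditioning paradigm, microglial and immediate early genes lay lower and sterol synthesis and myelin genes higher after cocaine. All 17 microglia markers were negative (mean -0.17, level 3.73 ± 0.068 against 3.90 ± 0.22, SD, n = 6 and 6). P2ry13 fell when adjusted over the list alone (2.16 ± 0.225 against 3.10 ± 0.420 FPKM, -0.37 ± 0.07), 1 of the 17, and 0 did over all genes tested. The values of P2ry12, another purine receptor, were 8.98 ± 1.53 and 11.3 ± 2.28 FPKM, and those of the complement gene C1qc 27.9 ± 4.23 and 33.0 ± 4.19. Of the immediate early genes 17 of 21 were negative (mean -0.12), with Junb at 10.3 ± 2.51 and 13.8 ± 1.55 FPKM and Ier5 at 3.47 ± 0.713 and 4.31 ± 0.282. Sterol synthesis genes were positive in 17 of 18 (mean 0.082), among them the cholesterol carrier Stard4 (0.15 ± 0.05) and the regulator Insig1 (0.14 ± 0.06), and myelin genes in 17 of 18 (mean 0.11), among them Trf (0.26 ± 0.08) and Mag (0.18 ± 0.06). The neuropeptide list had a mean of -0.23 with 18 of 26 negative, including neurotensin, Nts (6.93 ± 1.18 against 11.1 ± 3.28 FPKM), and the peptide precursor Adcyap1 (42.5 ± 6.68 against 58.4 ± 12.3). Apart from P2ry13, no member of these 5 lists passed, adjusted over the list alone or over all genes tested. Preset-correlation camera called all 5, with adjusted p = 7.26e-07 (microglia), 0.00195 (immediate early), 3.47e-04 (sterol), 8.53e-04 (myelin) and 0.0101 (neuropeptides). In each the call was lost, with adjusted p between 0.659 and 0.664 with an estimated correlation, and fry called 0 lists here. Single libraries, left out in turn after the data were seen, moved several of these: without saline library 0 the microglia mean was -0.099 (adjusted p = 4.67e-04 with the preset correlation) and the myelin mean 0.064, without cocaine library 3 the myelin mean was 0.063, and without cocaine library 0 the sterol mean was 0.044 (adjusted p = 0.0598). Without cocaine library 3 the neuropeptide call ended as well (-0.19, adjusted p = 0.0655).

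Limma called 0 of 13135 genes in conditioning, the smallest adjusted p being 0.147 for a predicted gene. At unadjusted p under 0.05 there were 1078 genes (516 higher, 562 lower, 657 by chance), 19 higher and 51 lower by at least 1.3-fold. Bhlhe22, a transcription factor of neurons, was 3.26 ± 0.351 FPKM after cocaine and 5.17 ± 0.918 after saline (-0.53 ± 0.09, adjusted p = 0.309; chromosome 3, 18054174 to 18057517, plus strand, GRCm38). The other lower genes, all at adjusted p = 0.591, included brain-derived neurotrophic factor, Bdnf (7.01 ± 1.03 against 9.48 ± 1.497 FPKM), the neuronal nitric oxide synthase Nos1 (6.07 ± 1.38 against 8.51 ± 1.24), the receptor tyrosine kinase Kit (-0.42 ± 0.10), the neuronal factor Nhlh2 (-0.45 ± 0.11), the peroxidase Gpx3 (-0.44 ± 0.11), Tspan18 (-0.48 ± 0.12), Gpsm3 (-0.45 ± 0.12), Kantr (-0.44 ± 0.12) and H2-L (-0.84 ± 0.20). H2-L is a class I histocompatibility gene of a multigene family, absent from the reference by that symbol, and its reads can be shared with its relatives. On the higher side, also at adjusted p = 0.591, were the potassium channel Kcna1 (52.3 ± 12.4 against 37.3 ± 10.5), Rimkla, an enzyme that makes the peptide transmitter NAAG (24.5 ± 3.35 against 17.9 ± 4.36), Gem (0.41 ± 0.14), Aldh3a1 (0.56 ± 0.20), Rassf4 (0.52 ± 0.19), Kctd9 (0.46 ± 0.17), Dnajc22 (0.47 ± 0.18), Rsc1a1 (0.48 ± 0.19), Cela1 (0.48 ± 0.19) and Fstl1 (0.41 ± 0.17). With the level of the myelin list as a covariate, 27 genes were left at unadjusted p under 0.05 and at least 1.3-fold, against 70 without it.

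After intravenous self-administration, clock genes were lower with cocaine than with saline. In the circadian clock list 15 of 17 members were negative (mean -0.14, level 3.68 ± 0.096, n = 15, against 3.82 ± 0.097, n = 9, SD). Adjusted over the list alone 5 fell, and 0 adjusted over all genes tested: the repressors Per1 (12.3 ± 1.65 against 15.3 ± 3.79 FPKM), Cry2 (27.6 ± 2.85 against 32.4 ± 4.89), Bhlhe40 (22.2 against 25.5 FPKM) and Bhlhe41 (10.4 ± 0.723 against 11.9 ± 1.32), and the output factor Tef (82.8 ± 5.38 against 90.5 ± 7.04). The activators Arntl (0.01 ± 0.07), Clock (-0.0049 ± 0.06) and Npas2 (0.03 ± 0.07) lay near 0. Preset-correlation camera gave adjusted p = 9.17e-10, fry adjusted p = 0.0498, and camera adjusted p = 0.0612 with an estimated correlation. An exact permutation of the list's level, added after the data were seen, gave p = 0.00314, or 0.176 adjusted over the 112 tests.

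**Figure D4:**
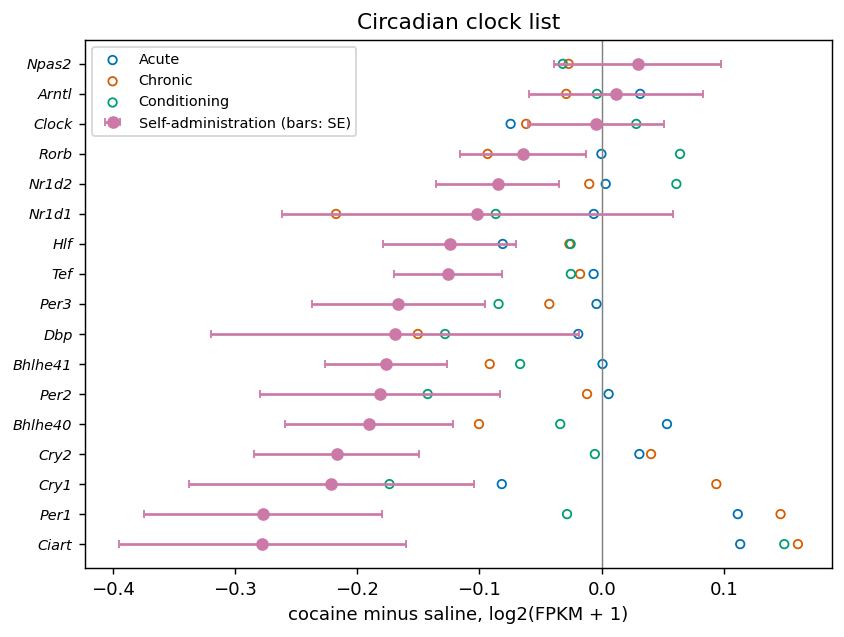
Difference between cocaine and saline on the log2(FPKM + 1) scale (x axis) for the 17 genes of the circadian clock list (y axis). Filled points with SE bars are self-administration, open points the other 3 paradigms; 15 of the 17 filled points lie below 0, the lowest at -0.28 for Ciart and Per1.

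Sterol synthesis genes were negative in 18 of 18 (mean -0.14) in self-administration, among them Hmgcs1 (110 ± 17.3 against 125 ± 16.2 FPKM) and Lss (10.3 ± 1.53 against 12.2 ± 2.98), with 0 past either adjustment. Markers of hypothalamus and mammillary body were negative in 7 of 8 (mean -0.59, median -0.19). Of these, 2 fell adjusted over the list alone and 0 over all genes tested: melanin-concentrating hormone, Pmch (10.2 ± 16.9 against 58.4 ± 66.4 FPKM), and hypocretin, Hcrt (0.706 ± 1.86 against 4.92 ± 5.86), both made by neurons of the lateral hypothalamus. The Pmch values of single saline libraries ran from 3.15 to 197 FPKM, and without any 1 library its difference stayed between -2.68 and -1.98. Within acute saline Pmch also varied widely, from 0.728 to 41.4 FPKM. Whether libraries held different shares of hypothalamic tissue was not tested, so an effect of cocaine on these genes cannot be told from that. Immediate early genes had a mean of 0.096 with 14 of 21 positive, Fos being 18.6 ± 4.18 and 14.9 ± 4.23, and interferon genes a mean of 0.095 with 12 of 16 positive, Irf9 being 0.16 ± 0.05, each with 0 past either adjustment. Preset-correlation camera called these 4 lists, with adjusted p = 2.97e-07, 2.45e-04, 0.0215 and 0.00431. They were lost, with adjusted p = 0.659, 0.659, 0.664 and 0.664 with an estimated correlation. With libraries left out in turn, the sterol mean was -0.081 without saline library 1, its call kept. The interferon call ended without cocaine library 6 (0.066) or saline library 0 (0.041) or 1 (0.046), and its mean was 0.15 without saline library 2. The immediate early call ended without cocaine library 2 (0.072), 6 (0.087) or 7 (0.077), or saline library 0 (0.067), 7 (0.079) or 8 (0.083).

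Among 13130 genes limma called 0 in self-administration (smallest adjusted p = 0.999), and 450 (212 higher, 238 lower) had an unadjusted p under 0.05 where chance would give 656.5. Of these, 9 were higher and 15 lower by at least 1.3-fold. The genes that filled the naming rule, all at adjusted p = 0.999, were on the higher side C1ql2, a secreted synaptic organiser (13.0 ± 9.41 against 5.24 ± 2.05 FPKM), its relative C1ql4 (0.57 ± 0.26), cholecystokinin, Cck (71.7 ± 20.3 against 49.98 ± 17.5), osteopontin, Spp1 (0.76 ± 0.32), the neurofilament Nefl (0.44 ± 0.21), the serotonin receptor Htr1d (0.46 ± 0.17), the myelin connexin Gjb1 (0.38 ± 0.13), Tesc (0.43 ± 0.18), Foxd2 (0.43 ± 0.18) and the protease Klk6 (0.40 ± 0.20). On the lower side, beside Fgf20, Pmch and Hcrt, were the homeobox factor Shox2 (-0.51 ± 0.19), the glucose transporter Slc2a4 (-0.42 ± 0.14), Tma16 (-0.40 ± 0.12), Snora43 (-1.55 ± 0.57), Parpbp (-1.40 ± 0.44) and Rn45s, the ribosomal RNA precursor (238 ± 54.0 against 358 ± 99.5 FPKM). Parpbp overlaps Pmch on chromosome 10 (88091432 to 88146941, minus strand, and 88091072 to 88092375, plus strand, GRCm38), so their reads cannot be told apart without strand. Fitting all 8 groups together called Sh3bp2 (-0.27, adjusted p = 0.00478) and Fam117b (-0.25, adjusted p = 0.0210).

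The genes of dopamine synthesis, transport and autoreception were compared in every paradigm. Th, the rate-limiting enzyme of dopamine synthesis, was 307 ± 179 after cocaine and 377 ± 95.3 FPKM after saline in acute, 424 ± 167 and 379 ± 194 in chronic, 337 ± 206 and 316 ± 132 in conditioning, and 258 ± 104 and 259 ± 119 in self-administration. Slc6a3 differed by -0.60, 0.19, -0.04 and -0.20 in the same order, Slc18a2 by -0.50, 0.19, -0.07 and -0.09, and the D2 receptor Drd2 by -0.39, 0.10, -0.07 and -0.00076. None of the 16 exact permutation tests passed (smallest adjusted p = 0.874). In chronic, conditioning and self-administration their signs turned under other settings, except that of Slc6a3 in self-administration, which ran from -0.32 to -0.07 without single libraries. In acute, leaving out cocaine library 4 gave -0.20 for Th, -0.34 for Slc6a3, -0.29 for Slc18a2 and -0.20 for Drd2.

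**Figure D5:**
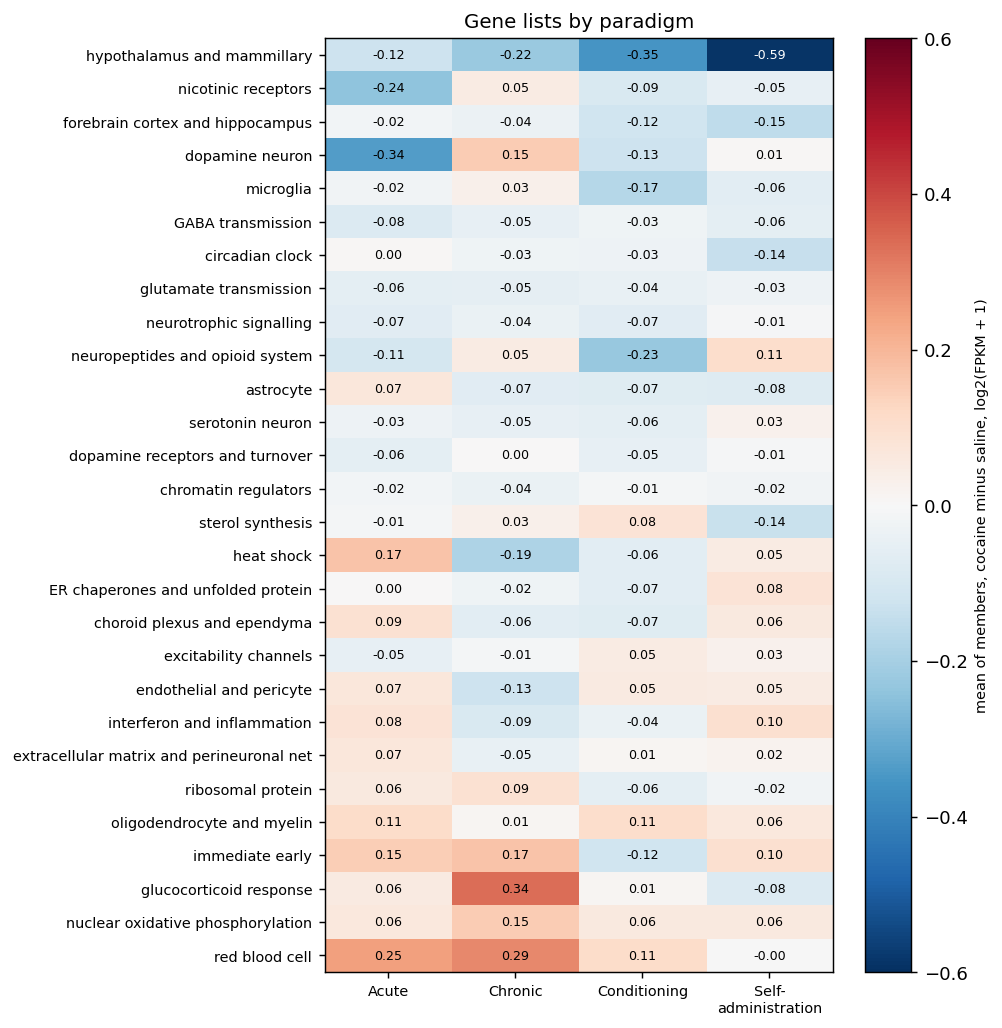
Mean difference between cocaine and saline over the members of each of 28 gene lists (y axis) in the 4 paradigms (x axis), on the log2(FPKM + 1) scale. Red cells are higher after cocaine and blue cells lower, from -0.59 (hypothalamus and mammillary, self-administration) to 0.34 (glucocorticoid response, chronic).

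The question in the study's title, whether the response to cocaine depends on the paradigm, was put to the differences between cocaine effects. The smallest p between chronic and self-administration was that of Sgk1, which differed by 0.75 ± 0.16 (0.68 against -0.07, adjusted p = 0.125), together with Polr3e, a subunit of RNA polymerase III (0.37 ± 0.08, adjusted p = 0.125). Sh3bp2, an adaptor protein, differed by 0.37 ± 0.08 between conditioning and self-administration (adjusted p = 0.209). The glucocorticoid list differed by 0.42 between chronic and self-administration, by 0.32 between chronic and conditioning and by -0.27 between acute and chronic, and the clock list by 0.14 between acute and self-administration. The sterol list differed by 0.22 between conditioning and self-administration and the dopamine neuron list by -0.49 between acute and chronic. These 6 were picked after their values were seen, from 52 list differences that preset-correlation camera called among 168. In the order given they had adjusted p = 2.58e-19, 9.57e-08, 5.64e-07, 5.64e-07, 5.79e-12 and 1.79e-07. They did not hold, with adjusted p = 0.0764, 0.428, 0.428, 0.179, 0.396 and 0.573 with an estimated correlation, and fry gave 0.437, 0.876, 0.955, 0.801, 0.876 and 0.955. Of the 168, the estimated correlation and fry each called 0. Limma called 0 genes in each of the 6 differences, with between 146 and 395 genes at unadjusted p under 0.05 where 659 would be there by chance. Setting aside the least correlated libraries, chosen after the data were seen, called Polr3e (adjusted p = 0.0186).

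The other genes the rule named for these differences had adjusted p of about 1. They were Pet117 (-1.76 ± 0.49) between acute and chronic, Rps19bp1 (0.36 ± 0.11) and Irf5 (0.35 ± 0.11) between acute and conditioning, Rrp8 (0.30 ± 0.08) and again Irf5 (0.34 ± 0.10) between acute and self-administration. Ndufaf3, an assembly factor of complex I, differed by 0.27 ± 0.07 between chronic and conditioning and by -0.23 ± 0.06 between conditioning and self-administration, and Tma16 by 0.60 ± 0.17 in the latter. Mirlet7c-2, Mir6990 and the pseudogene Atp6v0c-ps2, whose reads can be shared with Atp6v0c, filled the remaining places.

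Log2 differences of the paradigms were correlated across genes, which are not independent replicates. Pearson's r was 0.073 for acute and chronic, 0.198 for acute and conditioning, 0.182 for acute and self-administration, 0.131 for chronic and conditioning, 0.155 for chronic and self-administration, and 0.1997 for conditioning and self-administration, and Spearman's rho lay between 0.194 and 0.268. No pair passed against 100 relabellings within paradigms (adjusted permutation p of at least 0.436 over 6 pairs). The mean r of 0.156 compared with a relabelled median of -0.011 and a highest of 0.180 (one-sided permutation p = 0.0297). The permutation p given below for overlaps and shared genes are one-sided too, while those of the pairs' correlations are two-sided. At unadjusted p under 0.05, 215 gene overlaps between pairs of paradigms went the same way, where independent lists give 125 and the relabellings a median of 68 (permutation p = 0.0594), and 51 went opposite ways. Past that limit in the same direction in at least 3 paradigms were 8 genes (relabelled median 0, highest 33, permutation p = 0.0891). These were Fgf20, P2ry13, Fos, Pdrg1, the lysosomal sulfatase Ids, Cox4i1, Apbb1ip and a predicted gene. Fos differed by 0.62, 0.71 and 0.32 in acute, chronic and self-administration and by -0.09 in conditioning.

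Saline groups of the 4 paradigms were compared to see how the baselines differ. Glucocorticoid-responsive genes stood higher in self-administration saline than in the other saline groups, with a mean of 1.10 over 18 members and 17 of them positive, Plin4 being 19.6 ± 3.70 FPKM (n = 9) against 0.814 ± 0.293 (n = 6) in acute saline. Myelin genes stood lower (mean -0.55, 1 of 18 positive), and so did dopamine neuron markers (mean -0.45, 1 of 20 positive) and heat shock genes (mean -0.34, 2 of 15 positive). Other lists had means of 1.57 (red blood cells, 3 of 4 positive), 0.59 (hypothalamus, 5 of 8), 0.32 (interferon, 13 of 16), 0.21 (astrocytes, 12 of 16), 0.17 (GABA transmission, 18 of 21), -0.20 (oxidative phosphorylation, 17 of 53) and -0.23 (microglia, 2 of 17). The red blood cell mean held Hba-a2 at 4.67 and its near-identical copy Hba-a1 at -2.70, while the sum of both differed by 0.27. After a correction for GC content and transcript length within each library, added after the data were seen, oxidative phosphorylation was at -0.10 (19 of 53 positive), microglia at -0.13 (5 of 17) and ribosomal proteins at 0.17 (43 of 57), against 0.0066 (33 of 57) before it for the last. The myelin, dopamine neuron and heat shock means were then -0.53, -0.35 and -0.28. That of red blood cells was 1.81 ± 1.56 (SE over members). These lists were picked after their values were seen, and no test of lists was run between saline groups. Ier5l was 0.213 ± 0.076 FPKM in self-administration saline and 6.75 ± 1.23 in acute saline, Tpgs1 7.58 ± 1.61 and 48.5 ± 7.36, Ppp1r35 3.19 ± 0.766 and 20.5 ± 3.58, Hmg20b 4.10 ± 0.381 and 12.3 ± 1.48, and H2-L 0.051 ± 0.10 and 6.68 ± 1.12. The GC content of Ier5l, Tpgs1, Ppp1r35 and Hmg20b is 63.8%, 65.3%, 63.6% and 60.5%. Before the correction, the saline difference had a Spearman's rho of -0.38 with GC content across genes. Its median was -0.34 in the tenth of genes with the highest GC content (from 58.1%). Limma's moderated F test called 6455 of 13202 genes. Acute and chronic saline differed in 0 genes, acute and conditioning in 1, chronic and conditioning in 3, while self-administration saline differed from acute in 6143 (3140 higher, 3003 lower), from chronic in 6322 and from conditioning in 6627. The labels give no batch, all libraries of self-administration stand on one side, and paradigm and any batch cannot be told apart.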

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

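Tests chosen after the result was seen were those on endothelial cells and astrocytes and on near-identical copies; the others were fixed before their result was known. Of 105 combinations of a group and a measure, 12 held a library far from the rest of its group, where chance gives about 1 in 20. The self-administration cocaine group (n = 15) was too large for this screen and was left out of it. Its pituitary levels reached 1.95, 1.60 and 1.56 in libraries 10, 0 and 12, against a group median of 0.191. Acute cocaine library 4 had a highest correlation with any other library of 0.983 (others 0.991 to 0.993) and an oxidative phosphorylation level of 8.26 (others 7.95 to 7.97). Acute saline library 0 had a dopamine neuron level of 5.88 (others 5.19 to 5.44) and Th at 562 FPKM (others 293 to 368). The pituitary level was 0.706 in acute cocaine library 1 (others up to 0.138), 0.571 in chronic saline library 3 (others up to 0.108) and 2.78 in self-administration saline library 4 (others up to 0.255), which listed Gh at 701 FPKM. The endothelial level was 3.90 in conditioning cocaine library 0 (others 4.04 to 4.09) and 4.09 in chronic saline library 2 (others 3.94 to 3.99). Chronic saline library 3 had a microglia level of 3.96 (others 3.72 to 3.78). Conditioning saline library 2 listed 7142 genes at 0 (others 5985 to 6353) and had a highest correlation of 0.989 (others 0.991 to 0.992).

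Fgf20 was lower after cocaine in all 4 paradigms. In 3 of 100 relabellings of cocaine and saline, the real one included, as many genes passed as the real count of 1 (highest other 8). Relabelling thus seldom gave any call. The count covers any gene and does not test Fgf20 itself, which was picked from the same libraries, so chance is not excluded for it. Fewer dopamine neurons are argued against by a difference of -0.64 ± 0.07 with the dopamine neuron level as covariate. A different share of myelin-rich or hypothalamic tissue is argued against by -0.66 ± 0.12 with the myelin and hypothalamus levels as covariates. No other neighbouring tissue was used as a covariate in this fit, so a different share of other neighbours stays open. A low level near the floor stays open. At a pseudocount of 0.1 without a filter the difference was -1.14 ± 0.19 (limma adjusted p = 0.00293). That setting enlarges differences of low genes, and the read depth is unknown, so it cannot decide the question. A candidate explanation is that cocaine lowers Fgf20 mRNA in the VTA, a hypothesis found and tested on the same libraries, which separate samples would have to test. The call ended without the acute paradigm (adjusted p = 0.0646), the highest over its alternatives, whose lowest was 1.41e-08 with the dopamine neuron covariate.

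Glucocorticoid-responsive genes were higher after chronic cocaine, and 1 of 100 splits of the 12 libraries gave a list mean as far from 0, the real one (0.34, with the highest other at 0.28). The list stood out among 112 list tests that included these same libraries, and the splits do not allow for that choice. They therefore do not exclude chance for it. The values argue against more endothelial cells and astrocytes (their lists had a mean of -0.097 ± 0.03) and against a length or GC trend (0.33 ± 0.04 above matched genes). They also argue against a different time of day (gap of -0.0084 ± 0.041 between both arms of the clock) and against a single library (lowest mean 0.30 without any of the 12). The ± values here are SE over genes and leave out the spread between the 12 libraries. Explanations weighed by them are argued against only for these group means. A stronger stress hormone response after chronic cocaine may account for it, a hypothesis that hormone levels, which these data do not hold, would have to test. The list's level in chronic cocaine (4.06) was close to that in conditioning saline (4.05), where Sgk1 was 150 FPKM against 134 in chronic cocaine. Chronic and acute saline lay lower, at 3.72 and 3.79. A low level in chronic saline was therefore not told apart from a rise after cocaine. Handling or time since the last injection that differed between the groups stays open and untested. Fry called the list (adjusted p = 0.0150), and camera missed the threshold at adjusted p = 0.0612 with an estimated correlation.

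Saline libraries of self-administration differed from those of the other paradigms in 6143 to 6627 genes per pair, and the F test over the 4 saline groups called 6455, which 1 of 100 relabellings, the real one, reached (highest other 1). GC content and length are argued against as the whole cause: a correction within each library moved 5061 genes by over 0.1 and left 6261 genes, against 6414 before it. Whether reads of near-identical copies were assigned differently stays open: Atp6v0c and its pseudogene (-4.40 and 6.15, sum -0.094) showed the pattern it needs, the sum of Oaz1 and its pseudogene differed by 0.53 in size, between the bounds set, with Oaz1 itself at 0.31, and Hba-a1 and Hba-a2 (-2.70 and 4.67, sum 0.27) showed it in means of logs but not in mean FPKM (79.1 against 60.2, and 70.6 against 1.68). The glucocorticoid response list stayed higher by 1.19 ± 0.21 (SE over members) after the correction, beyond the GC and length trend, and what lies behind it was not tested. Library batch and paradigm cannot be told apart here.

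For the counts 100 splits of the same libraries were drawn for each, the real one included, and the numbers of splits below include it. Chance could not be excluded for the genes at unadjusted p under 0.05: 46 splits gave as many in acute (515; highest other 1960), 24 in chronic (974; 2677), 20 in conditioning (1078; 2496) and 55 in self-administration (450; 4147). With the 1.3-fold limit added, the counts were 16, 32, 70 and 24 in that order. Other splits reached as many in every paradigm (highest 144, 293, 186 and 202), so chance could not be excluded there. Nor could it for the lists called by preset-correlation camera, adjusted within the paradigm, in chronic (56 splits as many; 8 lists, highest other 14), conditioning (51; 8, 16) and self-administration (37; 9, 14). In acute 3 splits called as many lists (15; 16). For the average effect 6 splits gave as many genes at unadjusted p under 0.05 (1689; 2979), and for the 6 differences together 81 did (1534; 7722). Splits with several times the real count point to a structure of the samples, whose cause was not tested.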

How the results depend on the processing

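Alternatives chosen after the data were seen were setting aside the least correlated libraries, the dopamine neuron covariate, Fgf20 without each library in turn, permutation of list levels, lists without each library in turn, matched genes and the GC and length correction. No paired analysis was possible because the columns carry numbers counted from 0 that are not tied to the replicate numbers of the labels; the planned replicate block was not run. Of the counts and summaries, 214 held and 36 moved (for counts, by over 1.5 times). Of 6 lists' values 36 held and 12 lost the call. Of the named genes' values 4246 kept direction and side of the threshold, 62 changed sign, 12 passed only under the alternative and 1 lost its call. Genes at unadjusted p under 0.05 and 1.3-fold numbered 16, 32, 70 and 24 in acute, chronic, conditioning and self-administration. A pseudocount of 0.1 gave 46, 84, 129 and 46, since it enlarges differences of low genes, and a filter at 5 FPKM gave 5, 16, 34 and 12, since fewer genes are tested. No filter gave 26 in acute, library weights 42 in conditioning and 109 in self-administration, and the myelin covariate 27 in conditioning. Without single libraries the ranges were 13 to 49 in acute (49 without cocaine library 0, 35 without 1), 46 to 114 in conditioning (46 without cocaine library 3, 114 and 108 without saline libraries 3 and 4) and 19 to 47 in self-administration (47 and 40 without cocaine libraries 6 and 13, 37 without saline library 2). Genes past adjusted p numbered 1 in chronic with all groups in one fit (Sgk1, 0.0239), 2 in self-administration with that fit (Sh3bp2, Fam117b), 1 in conditioning with upper-quartile scaling or with library weights (a predicted gene, 0.0209 and 0.0375), 1 in self-administration with library weights (Spata33, 0.0330), and 0 to 1 in chronic without single libraries (Ddit4, 0.0174, without cocaine library 0, and Arrdc2, 0.0368, without saline library 0). For the average effect, library weights called 41, leaving out acute 0, leaving out self-administration 2 (Fgf20, P2ry13), the dopamine neuron covariate 3 (Fgf20, Inhbb, Trib2) and setting aside the least correlated libraries 2 (Fgf20, Trib2). Without each of the 59 libraries in turn Fgf20 stayed between -0.72 and -0.64, with adjusted p from 0.000194 to 0.00306. That same setting aside called 1 gene (Polr3e) between chronic and self-administration. Overlaps numbered 8 with the 1.3-fold limit, since fewer genes enter. Of 40 list calls, 0 held with an estimated correlation and 2 with fry. Without each library of the paradigm in turn, 17 kept the preset-correlation call throughout and 23 lost it at least once, and the mean moved by over 1.5 times in 24, with 1 change of sign (neurotrophic signalling in acute, 0.0071 without cocaine library 4). The cause was not tested unless given.

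The dopamine genes changed sign as follows, and the cause was not tested. Library weights gave in chronic Th -0.054, Slc6a3 -0.12, Slc18a2 -0.11 and Drd2 -0.14, in conditioning 0.31, 0.31, 0.21 and 0.19 in that order, and in self-administration Slc18a2 0.077 and Drd2 0.079. The myelin covariate gave in conditioning Th 0.27, Slc6a3 0.36, Slc18a2 0.21 and Drd2 0.21. With the least correlated libraries set aside, Slc18a2 was 0.053 and Drd2 0.094 in self-administration. Without single libraries Th ran from -0.0087 to 0.45 in chronic, -0.27 to 0.16 in conditioning and -0.086 to 0.16 in self-administration, Slc6a3 from -0.036 to 0.43 and -0.25 to 0.21 in the first 2, Slc18a2 from -0.050 to 0.40, -0.28 to 0.13 and -0.21 to 0.026, and Drd2 from -0.042 to 0.25, -0.24 to 0.11 and -0.058 to 0.10. Depth is unknown, so its limit on low genes could not be set.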

Other observations

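Several fixed lists had a preset-correlation camera call without being described above, with adjusted p between 1.71e-04 and 0.0484, and each was lost (lowest adjusted p = 0.659 with an estimated correlation, highest 0.794). In acute these were GABA transmission (mean -0.082, 17 of 21 negative), glutamate transmission (-0.058, 18 of 26 negative), neurotrophic signalling (-0.068, 12 of 17 negative), nicotinic receptors (-0.24, 7 of 8 negative), astrocytes (0.069, 12 of 16 positive), endothelium and pericytes (0.069, 15 of 16 positive), heat shock (0.17, 12 of 15 positive) and extracellular matrix (0.067, 15 of 22 positive). In chronic they were chromatin regulators (-0.041, 22 of 31 negative), heat shock (-0.19, 13 of 15 negative) and interferon (-0.092, 13 of 15 negative). In conditioning they were hypothalamus and mammillary body (-0.35, 5 of 5 negative), ER chaperones (-0.065, 14 of 18 negative), ribosomal proteins (-0.061, 40 of 57 negative) and oxidative phosphorylation (0.056, 47 of 53 positive). In self-administration they were oxidative phosphorylation (0.059, 48 of 53 positive), ER chaperones (0.082, 15 of 18 positive), GABA transmission (-0.058, 16 of 21 negative) and glucocorticoid response (-0.081, 14 of 18 negative). None of their members passed over all genes tested, and none passed adjusted over the list alone. With each library left out in turn, a setting added after the data were seen, the calls stayed for GABA transmission in acute and for oxidative phosphorylation in conditioning (means 0.021 to 0.092) and self-administration (0.029 to 0.087), and the other calls of this paragraph ended at least once. In acute, the ended calls had means of 0.0071 (neurotrophic), -0.098 (nicotinic) and 0.024 (endothelium) without cocaine library 4, -0.053 (glutamate) without cocaine library 0, 0.046 (astrocytes) without cocaine library 1, 0.097 (heat shock) without cocaine library 2 and 0.039 (extracellular matrix) without saline library 4. In chronic, they were -0.031 (chromatin) without saline library 0, and -0.059 (heat shock) and -0.067 (interferon) without saline library 5. In conditioning, they were -0.24 (hypothalamus) and -0.028 (ribosomal) without cocaine library 0 and -0.038 (ER chaperones) without saline library 4. In self-administration, they were 0.057 (ER chaperones) without saline library 4, -0.045 (GABA) without saline library 7 and -0.026 (glucocorticoid) without saline library 1. These are the libraries whose removal gave the highest adjusted p, and others also ended some of the calls. Other removals gave means of 0.033 for astrocytes and -0.043 for glutamate transmission in acute, and -0.21 for hypothalamus in conditioning.

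Not called in any paradigm were red blood cells, with means of 0.25, 0.29, 0.11 and -0.0014 in acute, chronic, conditioning and self-administration (median 0.21 in the last), dopamine receptors and turnover (-0.058, 0.0037, -0.048 and -0.0087), excitability channels (-0.050, -0.014, 0.049 and 0.027), choroid plexus and ependyma (0.093, -0.064, -0.074 and 0.057), serotonin neurons (-0.031, -0.051, -0.057 and 0.026) and forebrain (-0.015, -0.036, -0.12 and -0.15). The heat shock list differed by 0.36 between acute and chronic, which preset-correlation camera called (adjusted p = 3.53e-06) and which was lost, with adjusted p = 0.432 with an estimated correlation and 0.955 by fry. Among lists not called, mean and median differed in sign for the hypothalamus list in acute (-0.12 and 0.045), extracellular matrix in conditioning (0.010 and -0.027), and serotonin neurons (0.026 and -0.0074) and dopamine neurons (0.0050 and -0.00076) in self-administration. They also did for sterol synthesis (-0.011 and 0.0047) and forebrain (-0.015 and 0.0013) in acute, and for astrocytes in chronic (-0.067 and 0.0094, the test pointing downward). The test ran downward against a positive mean for the clock list in acute (0.0048), and for dopamine receptors (0.0037) and neuropeptides (0.051) in chronic.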
